A study of Mus musculus with 6 samples.

How the data were processed

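Gene expression was measured by RNA sequencing in 6 libraries made from parvalbumin-positive neurons of the mouse dorsal root ganglion at lumbar level 4, from C57BL/6 animals at postnatal day 21. The dorsal root ganglion holds the cell bodies of the sensory neurons that serve the body below the head, and parvalbumin marks mainly proprioceptive neurons there. Per the labels, 3 libraries were wild type and 3 carried a deletion of Dicer, the ribonuclease that cuts microRNA precursors into mature microRNAs, driven by a parvalbumin-Cre allele. The labels do not say whether each library came from a separate animal, so the p-values measure only the spread between these samples. Replicate 3 of each group differed in sex-linked transcripts from replicates 1 and 2, and so came from another animal. Between replicates 1 and 2 of a group the spread may be technical.

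Per the labels' protocols, total RNA was extracted with the PicoPure kit, turned into cDNA and amplified with an Ovation kit, and the sheared cDNA was ligated to adapters for sequencing. Amplification from small inputs adds noise, which is largest for rare transcripts. Per the submitters' processing notes, the tools included cutadapt, Bowtie2 and RSEM 1.2.7, with the mm10 genome build; the annotation is not given in the sources used here. The authors deposited 1 table of TPM values (length-scaled transcript shares), with 1 column per library and replicates not pooled. TPM divides estimated counts by transcript length and scales each library to 1000000, so a rise of abundant transcripts lowers the values of others, and no sequencing depth is kept. The depth of each library is therefore unknown, and no interval that needs it was computed. RSEM shares reads between similar transcripts by a model, so values of near-identical copies are uncertain, and a value listed at 0 can be a failed estimate.

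The table has 31469 rows with 31032 distinct names. Of these names, 8441 were uc identifiers that the table does not pair with symbols, 312 names were used by more than 1 row, and 25 had the form of a date, as spreadsheet software writes some symbols. Each row was kept as deposited, and where a gene list named a symbol with several rows, the row with the highest mean was used. Coordinates and 3' UTRs came from GENCODE vM21 on GRCm38, the assembly that mm10 names, and 98.6% of the names other than uc identifiers matched it by symbol or synonym.

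The test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with an intensity trend in the empirical Bayes step and genotype as the only term. Rows with a mean of at least 1 TPM over the 6 libraries entered (13787 rows). Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, knockout minus wild type, and understate changes of low rows. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1, so none is reported for single genes.

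The 24 gene lists were fixed from general knowledge before the data were examined, as were the main test, the rule for named genes and most alternatives. The 20 lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry, which asks whether a list's genes move one way and does not compare them with other genes. Other lists are given as values. Members not found by name in the table were Whrn, Maf, Unc13a, Acta2, Hba-a1, Hbb-bs, Hbb-b2, Hras, Drgx and Junb. Genes were counted as switched when at 0.5 TPM or less in every library of one group and at 2 TPM or more in every library of the other. For microRNA sites, the 3' UTRs of 12003 genes (87.8% of the tested names) were searched with Python 3.11.15 and NumPy 2.4.6 for 7-base sites of 19 microRNA families. Genes with and without a site were compared in a linear model with UTR length, UTR GC content and mean level. The coefficient was then ranked among other 7-mers with the same number of G and C bases and the same CpG count.

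The named genes were Dicer1 and Pvalb, the 15 largest rises and 15 largest falls among called rows with groups that did not overlap and at least 5 TPM in the higher group, up to 4 members of each list, and up to 8 genes switched in each direction. Gene models were passed over (1 among the rises and 2 among the falls). The rule did not foresee uc identifiers, and at most 2 per direction are printed, so that 2 were passed over among the rises and 4 among the falls. Genes named outside the rule are stated as such, and some genes that the rule picked are not reported here.

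The calling step was tested on simulated data for 13787 rows, in 10 runs with 200 changed genes. Values were drawn from normal distributions with the real means and with spreads smoothed by limma's empirical Bayes step, not the raw spreads. The rates below hold for such data. It recovered 12.8% of 1.5-fold changes, 51.2% of 2-fold changes and 90.2% of 4-fold changes, and 7.7% of calls were false. A list lowered by 1 log2 unit was called in 10 of 10 runs, and 0 of 190 unshifted lists were. Genes were simulated as independent, while the correlation estimated between genes of a real list reached 0.812. These runs therefore cannot show how often an unshifted list would be called in the real data. In the site test, 0.3 added to genes with a let-7 site came back as 0.327. The added value is far larger than the coefficients in the real data (0.04 for let-7 and for miR-124). It does not show whether effects of that size can be found. Alternatives covered the pseudocount, the filter, 3 rescalings, the variance model, library weights, a block for the replicate number, leaving out each library, list tests, site length and limits for switched genes. A term for sex, the Xist-expressing libraries alone, a satellite glia covariate, summed rows of shared names and removal of a transcript length trend were added after seeing the data.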

Results

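Transcript levels were compared between 3 wild-type and 3 Dicer knockout libraries of parvalbumin-positive neurons from the mouse lumbar 4 dorsal root ganglion at postnatal day 21. The comparison asks how the transcriptome of these neurons, most of them proprioceptors that report muscle length and tension, differs when Dicer is removed. Between 13237 and 13960 rows reached 1 TPM in a library, and the 10 highest rows held 10.1% to 11.8% of the total. Correlations of log2 values across rows were 0.949 to 0.968 within wild type, 0.963 to 0.973 within knockout and 0.925 to 0.964 between them. Replicate 3 of each group had Xist at 0.06 and 0 TPM and the Y-linked Ddx3y at 33.3 and 32.7 TPM, and the other 4 libraries had Xist between 22.2 and 69.5 TPM with Ddx3y at 0.02 TPM or less.

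Dicer1 (chromosome 12, 104687742 to 104751952, GRCm38) was at 36.7, 26.0 and 48.7 TPM in the wild-type libraries and at 24.0, 20.8 and 21.8 TPM in the knockout libraries. The means were 37.1 ± 11.4 and 22.2 ± 1.62 TPM (SD, n = 3 each), a log2 difference of -0.68 (SE 0.22, limma adjusted p = 0.104) that did not pass the test. All 3 knockout values lay below all 3 wild-type values. The whole-gene value does not isolate a deleted exon and so cannot show how complete the deletion was. Without wild-type replicate 2 the difference was -0.90 (adjusted p = 0.0412), and the adjusted p ranged from 0.0412 to 0.355 over the alternatives. Pvalb, which encodes the calcium-binding protein parvalbumin and also marked the collected cells, fell from 22.6 ± 2.71 to 7.23 ± 5.85 TPM (SD, n = 3 each; chromosome 15, 78191114 to 78206400). Its log2 fold change was -1.73 (SE 0.41, adjusted p = 0.0452). Knockout replicate 3 had 13.98 TPM against 4.02 and 3.69 in the other knockout libraries. Without it the change was -2.28 (adjusted p = 0.00441), while leaving out any other single library ended the call (adjusted p from 0.0804 to 0.149), and the range over all alternatives was 0.00441 to 0.153.

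**Figure D1:**
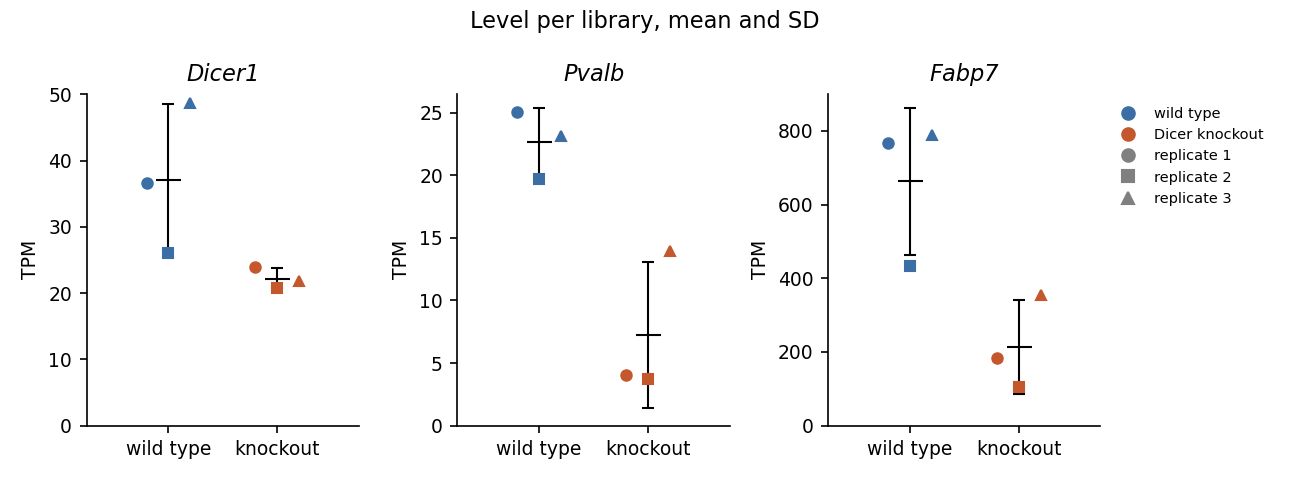
Levels of Dicer1, Pvalb and the satellite glia marker Fabp7 in TPM, with each symbol 1 library and bars showing the group mean ± SD (n = 3). All 3 knockout values lie below the wild-type values for each gene, and knockout replicate 3 is the highest knockout library for Pvalb (13.98 TPM) and Fabp7 (353.8 TPM).

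The largest falls included a channel subunit gene, neuropeptide genes and an axon guidance gene, beside a polyubiquitin row, a myosin gene and rows without a symbol. Vstm2b, which encodes an immunoglobulin-domain membrane protein, fell from 89.3 ± 8.99 to 4.63 ± 2.96 TPM (SD, n = 3; log2 fold change -4.19, SE 0.41, adjusted p = 0.00212; chromosome 7, 40898328 to 40930594). Kcnip2, an auxiliary subunit of A-type potassium channels, fell by 3.63 on the log2 scale (adjusted p = 0.00945). The neuropeptide genes Tac1, which encodes substance P, and Cartpt fell by 3.57 and 2.69, and Inhbb, which encodes an activin subunit, fell by 3.18. Rasd2, a small GTPase of the Ras family, fell by 2.97 and Pln, which encodes the calcium pump regulator phospholamban, fell by 2.75. Wls, which carries Wnt proteins to the cell surface, fell from 42.4 ± 9.26 to 6.04 ± 4.67 TPM. Slit3, an axon guidance ligand, went from 7.28 ± 0.88 to 0.16 ± 0.20 TPM (chromosome 11, 35121224 to 35708507). D7Ertd443e fell by 2.85. Crisp1 and Myl2, which encodes a myosin light chain, were called lower and were listed at 0 in each knockout library. One of the 2 rows named Ubb, a polyubiquitin gene, fell by 4.44, from 1107 to 52.4 TPM, while the other row rose by 0.49, from 2654 to 3716 TPM, and the 2 rows summed to 3761 ± 329 and 3768 ± 153 TPM. The identifiers uc029uip.1 and uc008joj.1, which the table does not pair with symbols, fell from 50.2 to 0.05 TPM and from 70.4 to 1.19 TPM.

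The largest rises included Serpina3n, S100a6, Tagln2, Basp1 and Cdkn1a. Serpina3n, a serine protease inhibitor, rose from 74.8 ± 17.1 to 229 ± 24.2 TPM (SD, n = 3; log2 fold change 1.62, SE 0.17, adjusted p = 0.00289; chromosome 12, 104406729 to 104414329), and its neighbour Serpina3i rose by 1.76 on the log2 scale (adjusted p = 0.0285). S100a6, a small calcium-binding protein, went from 197 ± 118 to 587 ± 98.4 TPM (adjusted p = 0.025). Tagln2, an actin-binding protein, and Basp1, a membrane protein of growing axons, rose by 1.53 and 1.61, and Eml1, a microtubule-associated protein, rose by 1.55 in 1 of its 2 rows. Cdkn1a, the cell cycle inhibitor p21, rose from 7.55 ± 1.97 to 23.2 ± 5.16 TPM (adjusted p = 0.0117). Rises were also called for Fxyd5, a regulator of the sodium-potassium pump (1.77), for Tspo, a protein of the outer mitochondrial membrane (1.77), for Gstm6, a glutathione transferase (2.15), and for Crybb3, a beta crystallin (1.88). Clec18a rose by 2.16 and Tmem176b by 1.78. The identifier uc008ogv.1 was listed at 0 in each wild-type library and at 67.8, 75.8 and 108 TPM in the knockout libraries, and uc008jok.1 went from 6.14 to 61.7 TPM. The row uc008joj.1, whose identifier precedes uc008jok.1, was among the largest falls (70.4 to 1.19 TPM). Whether reads moved between uc008joj.1 and uc008jok.1 was not tested.

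Over all rows, 256 rose and 437 fell in knockout libraries out of 13787 tested with limma. The groups did not overlap in any of the 693 called rows, and 28.9% of tested rows had groups that did not overlap, against 10% by chance. Changes of at least 1 log2 unit were called for 94 rises and 237 falls, and of at least 2 log2 units for 6 rises and 61 falls. With median-of-ratios rescaling, 375 rose and 385 fell, so that rises made up 49.3% of calls in place of 36.9%. The counts fell to 131 and 194 without wild-type replicate 2, 99 and 166 without wild-type replicate 3, 48 and 116 without knockout replicate 1, and 88 and 168 without knockout replicate 2; they were 65 and 139 in the 4 Xist-expressing libraries, and 100 and 134 with the satellite glia level as a covariate. Of the 30 largest changes, 6 of 15 rises (uc008ogv.1, Crybb3, Fxyd5, Serpina3n, Eml1 and Tagln2) and 13 of 15 falls (all but Wls and uc008joj.1) stayed called whichever single library was left out. Over the 62 called genes that the naming rule picked, the call was lost for 11, 20 and 25 genes without wild-type replicates 1, 2 and 3 and for 35, 28 and 11 genes without knockout replicates 1, 2 and 3.

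**Figure D2:**
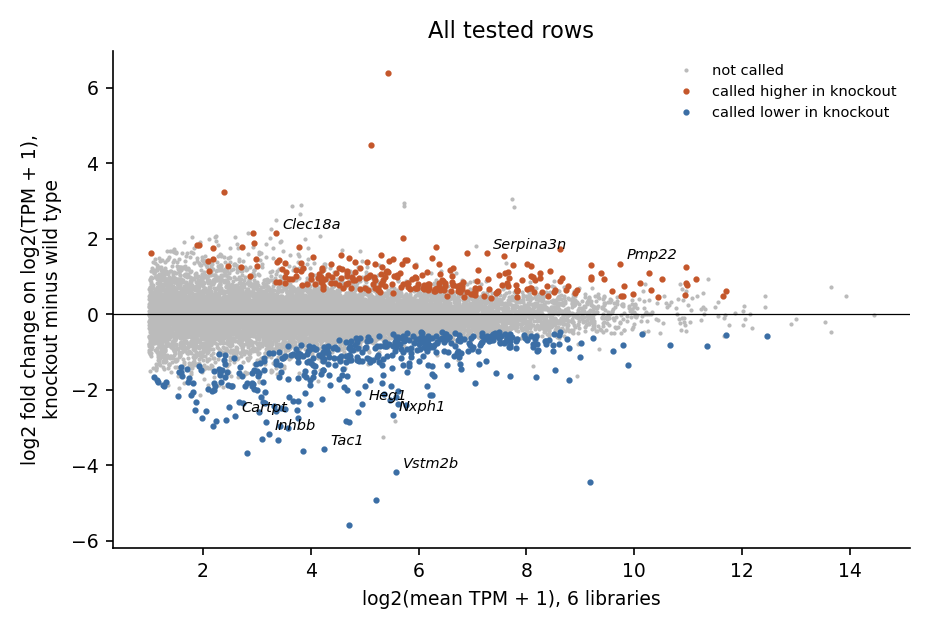
Log2 fold change (knockout minus wild type, on log2(TPM + 1)) of each of the 13787 tested rows against the log2 of its mean TPM + 1 over the 6 libraries, with each point 1 row. The 256 rows called higher and the 437 called lower are coloured, and the 61 falls of at least 2 log2 units outnumber the 6 such rises.

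Most of the genes listed as distinguishing proprioceptors from other sensory neurons fell. Of 15 tested members of the proprioceptor identity list, 10 fell, 1 rose and 4 did not pass the test, and 11 fell and 2 rose when adjusted over the list alone. Besides Vstm2b, the falls were largest for Nxph1, a secreted ligand of neurexins, from 78.3 ± 17.1 to 11.2 ± 0.49 TPM (log2 fold change -2.68, adjusted p = 0.000273), for Wnt7a (-2.59, adjusted p = 0.015) and for Heg1, from 51.1 ± 3.41 to 9.05 ± 0.85 TPM (-2.37, adjusted p = 0.000273). Transcription factors of the lineage fell as well. Runx3, needed for proprioceptor specification, fell by 1.59 (adjusted p = 0.0169), Etv1 by 0.89 (adjusted p = 0.0153), and the estrogen-related receptors Esrrb and Esrrg changed by -1.82 and -1.32. Spp1, which encodes osteopontin, fell by 1.47. Cdh13, a cadherin, rose by 0.95. Ntrk3, the neurotrophin-3 receptor on which proprioceptors depend, was at 198 ± 26.5 and 142 ± 32.3 TPM (log2 difference -0.50, adjusted p = 0.141), and the glutamate transporter Slc17a7 at 242 ± 1.75 and 219 ± 13.8 TPM (adjusted p = 0.43). The list's median log2 fold change was -1.47 and its mean -1.29 (camera adjusted p = 2.74e-06; adjusted p = 0.305 with an estimated correlation, the highest over the alternatives, which ranged from 8.75e-08; fry adjusted p = 0.00533). The satellite glia markers Fabp7 and Gja1 were also lower in these knockout libraries, and with the satellite glia level as a covariate the list's median was -1.27 and 5 of the 10 falls stayed called.

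**Figure D3:**
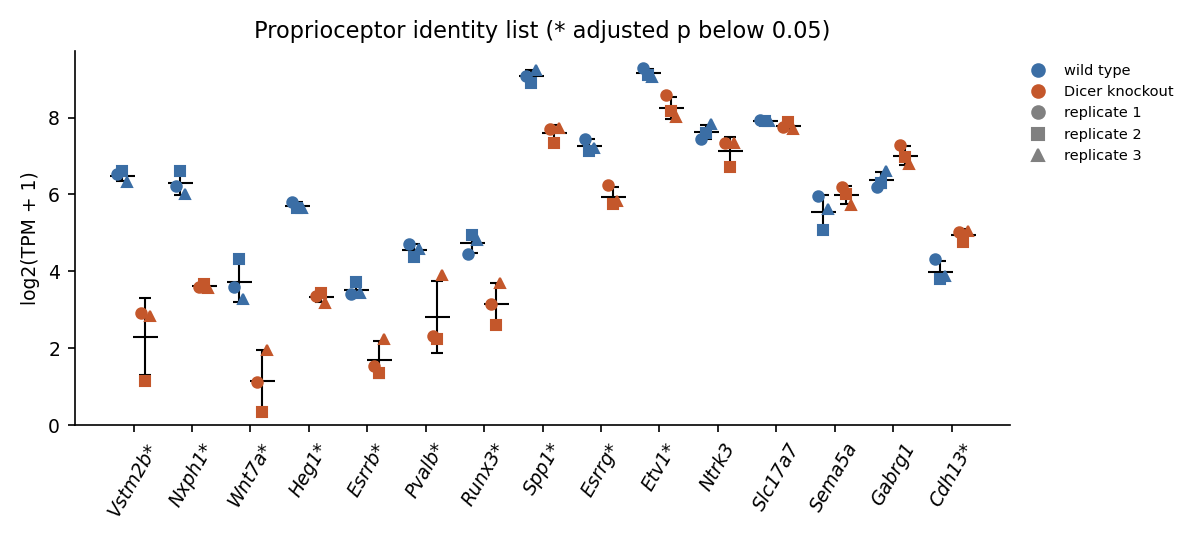
Level of each tested member of the proprioceptor identity list as log2(TPM + 1), with each symbol 1 library, bars showing the group mean ± SD (n = 3), and an asterisk for an adjusted p below 0.05. The members run from the largest fall, Vstm2b (-4.19), to the rise of Cdh13 (0.95).

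Markers of other sensory neuron classes moved in both directions. Of 13 tested genes of low-threshold mechanoreceptors, which sense touch, Ret, a receptor tyrosine kinase, rose by 0.93, while Calb2, which encodes calretinin, Ldhb and Cntnap2 fell by 1.26, 0.81 and 0.62; 9 did not pass (2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.858). Of 11 peptidergic nociceptor genes, Calcb, which encodes a calcitonin gene-related peptide, rose by 0.98, while Tac1 fell by 3.57 and Adcyap1, which encodes the peptide PACAP, fell from 48.4 ± 6.25 to 20.4 ± 2.26 TPM (4 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.683). Gfra2, a co-receptor for neurturin, rose by 1.48 and was the only call among 6 non-peptidergic nociceptor and itch genes (1 higher adjusted over the list alone, camera adjusted p = 0.316). Among 16 pan-neuronal genes, Rbfox3, which encodes NeuN, rose by 0.46 and 15 did not pass (1 higher adjusted over the list alone, camera adjusted p = 0.98).

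Several genes of membrane excitability and transmitter release changed, and neither list passed the test. Of 16 genes of ion channels and mechanotransduction, Kcnc1, a fast-gating potassium channel subunit, fell from 89.7 ± 13.8 to 16.5 ± 5.54 TPM (log2 fold change -2.42, adjusted p = 0.00224). Kcns1, Asic2 and Asic1 fell by 1.27, 1.15 and 1.02, and the acid-sensing channel gene Asic3 rose by 1.11 (adjusted p = 0.00434). The other 11 did not pass (2 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.316). Of 19 presynaptic genes, Vamp2, a synaptic vesicle fusion protein, and the glutamate transporter Slc17a6 rose by 1.01 and 0.53, while the vesicle protein gene Sv2a fell by 1.92. In all 2 rose, 2 fell and 15 did not pass (2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.98).

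Transcripts of satellite glia, the cells that wrap sensory neuron bodies, were present in every library and lower in the knockout group for 2 of 12 tested markers. Fabp7 fell from 663 ± 200 to 214 ± 128 TPM (log2 fold change -1.75, adjusted p = 0.0412) and Gja1 from 7.14 ± 2.65 to 1.80 ± 0.80 TPM (-1.53, adjusted p = 0.0408). Apoe was at 394 ± 226 and 160 ± 104 TPM (adjusted p = 0.133). The list had 2 falls adjusted over the list alone, a median of -0.61 and a camera adjusted p of 0.14 (adjusted p = 0.87 with an estimated correlation, of 0.812 between its genes, and 0.533 by fry). At the preset correlation it passed the threshold with a replicate block (0.00122), a sex term (0.0171), library weights (0.0263) and quantile normalization (0.0486). It also passed without wild-type replicate 2 (0.000159) or knockout replicate 3 (0.018), and its adjusted p ranged from 0.000159 to 0.953 over the alternatives. The 0.953 came with the satellite glia covariate, which is the mean level of this same list and so cannot test it. Among the other alternatives the highest was the 0.87 with an estimated correlation. Of 6 myelinating Schwann cell genes, Pmp22, which encodes a myelin protein that neurons can also express, rose from 480 ± 39.4 to 1223 ± 178 TPM (log2 fold change 1.34, adjusted p = 0.00212), and 5 did not pass (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.779). None of 6 fibroblast genes passed limma, and 0 had an unadjusted p below 0.05; the median was -0.05, with a mean of 0.07 and a test direction of higher (0 adjusted over the list alone, camera adjusted p = 0.795), and Dcn was at 25.4 ± 9.16 and 23.7 ± 7.05 TPM. Too few members reached 1 TPM to test the macrophage (1 member), endothelial and mural (4), erythroid (3) and skeletal muscle (2) lists, and 0 of these members passed limma; at an unadjusted p below 0.05 the macrophage gene Lyz2 was lower, and 1 erythroid member was higher and 1 lower. Lyz2 was at 7.05 ± 1.03 and 3.91 ± 1.195 TPM, the endothelial gene Egfl7 at 15.2 ± 2.88 and 18.8 ± 3.39 TPM, the haemoglobin gene Hba-a2 at 10.5 ± 7.88 and 35.6 ± 21.4 TPM, and the muscle actin gene Acta1 at 0.81 ± 1.21 and 1.86 ± 1.17 TPM.

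A few nuclear genes of the mitochondrial respiratory chain fell, and the call of their list depended on the test. Of 16 tested oxidative phosphorylation genes, Ndufb9 and Ndufs1, subunits of complex I, and Cycs, which encodes cytochrome c, fell by 0.69, 0.59 and 0.58, and 13 did not pass (1 higher and 6 lower adjusted over the list alone). The median log2 fold change was -0.29 (camera adjusted p = 0.00402; adjusted p = 0.825 with an estimated correlation, the highest over the alternatives, which ranged from 6.89e-05; fry adjusted p = 0.189). Of 20 lists tested with camera, this and the proprioceptor list were the 2 called lower; 0 were called higher, with 1 at an unadjusted p below 0.05 and 0 by fry.

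A few stress genes changed, and no axon injury gene passed the test. Of 12 p53 and apoptosis genes, Cdkn1a rose and Aen, an exonuclease induced by p53, fell by 1.13 (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.874). Of 13 unfolded protein and heat shock genes, the small heat shock protein gene Hspb1 rose from 336 ± 20.4 to 838 ± 123 TPM (log2 fold change 1.31, adjusted p = 0.00197), while the endoplasmic reticulum chaperone genes Hspa5 and Hsp90b1 fell by 0.69 and 0.56 (2 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.749). None of 14 axon injury and regeneration genes passed limma (3 higher and 1 lower at an unadjusted p below 0.05, 0 adjusted over the list alone). Their median was 0.51 (camera adjusted p = 0.157, and adjusted p = 0.87 with an estimated correlation); the list passed the threshold without wild-type replicate 3 (0.0296) and without knockout replicates 1 (0.0173) or 3 (0.018), and in the Xist-expressing libraries alone (median 1.01, 0.00158), and its median was -0.04 without knockout replicate 2, with adjusted p from 0.00158 to 0.992 over the alternatives. Among them Jun was at 93.0 ± 12.9 and 71.8 ± 8.59 TPM and Gap43 at 49.2 ± 21.3 and 64.9 ± 18.9 TPM. None of 7 interferon response genes passed (3 lower at an unadjusted p below 0.05, 3 lower adjusted over the list alone, camera adjusted p = 0.316), with Ifitm3 at 13.2 ± 5.62 and 15.6 ± 2.77 TPM. Of 10 immediate early genes, Fos rose by 0.80 (1 higher adjusted over the list alone, camera adjusted p = 0.316, and 0.0451 with a filter at a mean of at least 5 TPM). None of 10 genes of developing neurons and progenitors passed (2 higher at an unadjusted p below 0.05, 2 higher adjusted over the list alone, camera adjusted p = 0.316), with Stmn1 at 89.8 ± 8.08 and 112 ± 22.1 TPM.

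Lists tied to microRNAs showed little change. None of 13 genes of the microRNA pathway passed limma (1 lower at an unadjusted p below 0.05, 0 adjusted over the list alone, camera adjusted p = 0.779), and Ago3, which encodes an Argonaute protein, was at 40.0 ± 5.89 and 45.6 ± 1.64 TPM. Dicer1, the deleted gene, is itself a member of this list and of the let-7 list (log2 difference -0.68). It was the only member of either list that was lower at an unadjusted p below 0.05. Of 11 known targets of let-7, Plagl1, a zinc finger transcription factor, rose from 29.7 ± 4.36 to 61.1 ± 13.6 TPM (adjusted p = 0.0201), and 10 did not pass (1 higher adjusted over the list alone, camera adjusted p = 0.324). None of 13 targets of miR-124 passed (2 higher and 1 lower at an unadjusted p below 0.05, 0 adjusted over the list alone, camera adjusted p = 0.779), with Itgb1 at 212 ± 18.7 and 191 ± 20.98 TPM.

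Genes with microRNA sites in their 3' UTR were compared with genes without, for 16 families expected in neurons and 3 not expected there. Genes with a let-7 site (1287 genes) had fold changes higher by 0.04 on the log2 scale, at percentile 98.4 of matched 7-mers, and genes with a miR-124 site (1925 genes) by 0.04, at percentile 98.7. These 2 of 16 families lay in the top 2.5% of matched 7-mers and 0 lay in the bottom 2.5%. All 3 families not expected in neurons also lay in the top 2.5%, miR-1 at percentile 99.5, miR-122 at 99.1 and miR-133 at 98.8. With 6-base sites, 0 of 16 families lay above the limit, and 1 did without wild-type replicate 1 and without knockout replicates 2 or 3. Genes are not replicates, so these ranks describe these libraries.

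Few genes passed from near absence to presence or the reverse. By the limits of 0.5 and 2 TPM, 2 rows, both uc identifiers, were switched on and 10 were switched off in knockout libraries. Slit3 was at 7.02, 8.27 and 6.56 TPM in wild type and at 0.39, 0 and 0.10 TPM in knockout, and the protocadherin gene Pcdh8 at 5.17, 6.21 and 4.04 TPM and at 0.22, 0.12 and 0.26 TPM. Crisp1 was at 9.64, 4.44 and 7.22 TPM, Myl2 at 3.87, 7.79 and 6.03 TPM and Xlr4c at 2.14, 2.80 and 6.49 TPM in wild type, and each was listed at 0 in every knockout library. The number switched on was 16 without wild-type replicate 1, 4 without wild-type replicate 2, and 5 and 9 without knockout replicates 2 and 3. The number switched off was 17 without wild-type replicate 2 and 18 without knockout replicate 1 or 3.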

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

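The sex term, the Xist-expressing libraries, the satellite glia covariate, the summed rows and the length correction were chosen after seeing the data. The 256 rises became 130 with no filter, 389 with quantile normalization, 57 without the variance trend, 65 in the Xist-expressing libraries, 100 with the glia covariate and 644 at an adjusted p below 0.10. The 437 falls became 248, 168, 139, 134 and 962 with no filter, without the trend, in the Xist-expressing libraries, with the glia covariate and at 0.10. Leaving out 1 library gave 48 to 348 rises and 116 to 487 falls; a library fewer leaves less power, and the cause of the rest was not tested. Lists called higher went from 0 to 1 at a mean of at least 5 TPM (immediate early genes) and in the Xist-expressing libraries (axon injury and regeneration), and were 0 to 1 without single libraries. Lists called lower went from 2 to 0 with an estimated correlation and to 1 with fry, and to 3 with quantile normalization, library weights, a replicate block, a sex term, and without wild-type replicate 2 or knockout replicate 3. The proprioceptor list, at -1.475 with an adjusted p of 0.305 under an estimated correlation, passed the threshold in the other 23 of 24 alternatives. Switched on genes were 5 at limits of 0.1 and 1 TPM and 2 to 16 without single libraries; switched off genes were 3 at limits of 1 and 5 TPM and 14 to 18. Site families above the limit were 0 with 6-base sites and 1 to 2 without single libraries. Over the named genes, no alternative reversed a call; 1505 gene results stayed on their side of the threshold, 284 lost the call and 3 gained it, and for lists the numbers were 463, 3 and 11.

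Libraries with the same replicate number did not deviate together (correlations of 0.049, 0.066 and 0.038), and wild-type replicate 3 correlated best with knockout replicate 1 (0.07). A replicate block gave 188 rises and 341 falls, among them 162 and 304 of the calls made without it. It also called the satellite glia list lower (adjusted p = 0.00122), at the preset correlation of 0.01 where 0.812 was estimated (adjusted p = 0.87). That list's adjusted p ranged from 0.000159 to 0.953 over its alternatives, the 0.953 with the glia covariate, which is made from the list itself. Depth is unknown, so counting error could not be separated from other spread.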

Other observations

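The groups and genes in the following paragraph were chosen after their values were seen. Fxyd7, a small membrane protein of the same family as Fxyd5, rose from 797 ± 95.7 to 1678 ± 165 TPM (SD, n = 3; limma adjusted p = 0.00403). The potassium channel interacting proteins split, with Kcnip1 falling from 71.9 ± 7.70 to 14.6 ± 5.14 TPM (adjusted p = 0.00311) and Kcnip3 rising from 205 ± 34.8 to 400 ± 54.6 TPM (adjusted p = 0.0127). Both serotonin receptor channel subunits rose, Htr3a by 1.43 and Htr3b by 1.48 on the log2 scale (adjusted p = 0.0285 and 0.0371), as did the neurotrophin gene Bdnf by 1.22 (adjusted p = 0.0268). The calls of Htr3a and Htr3b ended without wild-type replicates 1 or 3 or knockout replicates 1 or 3, that of Bdnf without wild-type replicates 2 or 3 or knockout replicates 1 or 2, and that of Kcnip3 without knockout replicate 1. Over the alternatives the adjusted p reached 0.149 for Htr3a, 0.188 for Htr3b, 0.1 for Bdnf and 0.0683 for Kcnip3. The carbonic anhydrase gene Car2 fell from 438 ± 45.5 to 137 ± 15 TPM (adjusted p = 0.000485), and the morphogen gene Shh from 80.2 ± 12.8 to 30.3 ± 3.34 TPM (adjusted p = 0.00355).

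Groups of symbols were also tested with camera after their values were seen, over 7 groups. Of 36 complex I subunit genes, 6 fell and 0 rose (13 lower and 3 higher at an unadjusted p below 0.05), with a median of -0.17, which stayed negative under both rescalings (-0.09 and -0.17; adjusted p = 0.00948, and adjusted p = 0.506 with an estimated correlation). Among these falls were those of Ndufa9 (-0.98) and Ndufb5 (-0.88), whose calls ended without knockout replicate 1, that of Ndufa9 also without wild-type replicates 2 or 3 or knockout replicate 2. None of 15 complex IV genes passed limma (3 higher and 3 lower at an unadjusted p below 0.05, adjusted p = 0.253), nor did any of 17 ATP synthase genes (1 higher and 3 lower, adjusted p = 0.613); the difference between complexes was not tested. Of 22 Hox genes, Hoxb5, Hoxb6 and Hoxd1 rose by 0.92, 1.04 and 0.92 and none fell (7 higher and 2 lower at an unadjusted p below 0.05), with a median of 0.42 (adjusted p = 0.0249, adjusted p = 0.169 with an estimated correlation). The Hox median was 0.47 and 0.48 under the rescalings and 0.24 with the glia covariate, which ended the group's call (adjusted p = 0.138), and each of the 3 gene calls ended whichever library was left out, except that Hoxd1 stayed called without wild-type replicate 1. Of 5 Fxyd genes, Fxyd5 and Fxyd7 rose and none fell (3 higher at an unadjusted p below 0.05, median 1.08, adjusted p = 0.00338, adjusted p = 0.169 with an estimated correlation). Of 28 voltage-gated potassium channel genes 1 rose and 4 fell (median 0.17, mean -0.04, adjusted p = 0.667). The 30 rows named for microRNA genes had a median of 0.65 and 0 calls by limma (4 higher and 0 lower at an unadjusted p below 0.05). Their camera adjusted p was 0.0453, with 0.506 at an estimated correlation, and 0.211 and 0.267 with median-of-ratios rescaling and quantile normalization. Most of these rows had a mean of 0 TPM in one group, such as Mir377 (10.56 in wild type, 0 in knockout) and Mir343 (0 and 6.06). The median therefore does not show a general rise of microRNA genes. Among 56 families of symbols with at least 20 members, the Rpl ribosomal protein genes had a median of 0.17 (46 members, 1 higher, adjusted p = 0.000781, adjusted p = 0.964 with an estimated correlation, and 0.654 with the glia covariate) and Dnajc genes a median of -0.27 (26 members, 1 lower, adjusted p = 0.0314, adjusted p = 0.964 with an estimated correlation, and 0.0563 with median-of-ratios rescaling).

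The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 693 genes and the highest of the others called 1, and it had 12 switched genes against 5 at most, so that 1 of 10 splits reached each real count. For lists, 8 of 10 splits called as many as the real 2, and the highest other called 4. The proprioceptor list had a camera adjusted p of 2.74e-06 in the real split and 0.0188 at the lowest elsewhere. Every other split mixes the genotypes within its groups, so any difference between genotypes widens the spread there and lowers the counts. The contrasts in called genes, switched genes and the proprioceptor list are therefore not made against a chance level. For microRNA families, 2 of 10 splits gave as many as the real 2, and the highest other gave 2. By the rule set beforehand, more than 2 of 16 families above the limit counted for lower microRNA activity and 2 or fewer against it. The count was 2, at the bound, which by that rule counted against it, and after it was seen the test was read as undecided. All 3 families not expected in neurons also lay above the limit, so a high rank was not particular to expected families.

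Of the tests in the next paragraphs, those of low-threshold mechanoreceptors, of rises near Dicer1 and of the Ubb rows were chosen after the result was seen. The satellite glia covariate and the length correction used below were likewise chosen after seeing the data. The fall of proprioceptor genes was weighed against a changed mixture of cells and against length bias. Other neurons in the knockout samples would raise their own markers. The pooled median of the nociceptor lists was 0.227 (bootstrap SE 0.243, below the 0.5 set beforehand by little more than that SE), and that of the low-threshold mechanoreceptor list was -0.294 (SE 0.338). Most tested nociceptor genes had positive changes, 8 of 11 peptidergic and 5 of 6 non-peptidergic and itch genes. The pooled median therefore does not exclude some added nociceptors. In the low-threshold mechanoreceptor list 6 genes had positive and 7 negative changes, with Ret called higher and Calb2, Ldhb and Cntnap2 called lower. Its median likewise does not exclude some added mechanoreceptors. Of 17 nociceptor members 2 rose (Calcb and Gfra2) and 2 fell (Tac1 and Adcyap1), with Scn10a at 1.93 and Scn11a at 1.42 not passing. The 10 proprioceptor falls ran from -0.889 to -4.192 (median SE 0.228), not by a common factor. Dilution would give a common factor only if the added cells held none of these transcripts, so unequal falls do not exclude cells that hold some. After removing a length trend the median went from -1.475 (SE 0.436) to -1.466, so that length does not account for the fall; with the satellite glia level as a covariate it was -1.268 (SE 0.403) and 5 of the 10 calls ended, but this decides nothing, as fewer glia would raise the neuronal share and not lower it. A gain of a single neuron subtype that itself expresses some of these genes, a loss of the proprioceptors with the highest levels, and lower transcript levels per cell after Dicer removal stay open as hypotheses, since the libraries pool cells.

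Serpina3i, Serpina3n and Eml1, 3 of the 13 named rises with coordinates on autosomes, lie within 10 Mb of Dicer1 on chromosome 12, where 123 tested rows lie (odds ratio 30.4, 95% interval 5.31 to 120, Fisher's exact test, two-sided, p = 0.000259), but these genes were picked for their size. Serpina3i and Serpina3n are also neighbours of one gene family, as is Serpina3f, another called rise nearby. Fisher's test takes genes as independent, here and in the next comparisons. Over the rises with coordinates on autosomes the odds ratio was 2.22 (0.702 to 5.41, 5 of 123 against 228 of 12190, Fisher's exact p = 0.0841), and over all such calls 0.967 (0.346 to 2.18, 6 of 123 against 614 of 12190, Fisher's exact p = 1). Passenger alleles around a targeted Dicer1 locus may raise or mismeasure such genes, and cannot be told apart here from an effect of Dicer loss, because the locus goes with the genotype in all 6 libraries. By the rule set beforehand an odds ratio of 1 or less over these calls counted against such alleles; after it was seen it was read as undecided, since its interval includes 1.

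The opposite changes of the 2 Ubb rows leave their sum level, with a log2 difference of 0.005 between groups. This is consistent with reads moved between rows of near-identical transcripts rather than with a change in Ubb output, as a hypothesis. A sequence difference between the animals, or different handling of the libraries, may have moved them, and neither was tested.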
